A study of Mus musculus with 12 samples.

How the data were processed

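Single-cell 5' expression and T cell receptor libraries were made from sorted tumour T cells of 3 isotype and 3 anti-ACBP mice, per the labels' protocols. The deposited matrices hold UMI counts per gene and barcode, whole numbers that were not scaled. The submitters' processing notes list Cell Ranger 7.0.0, Seurat and the mm10 build and give no role for each. The deposited matrices held 69249 barcodes and 32285 gene symbols, and a deposited metadata table listed 30749 cells with a cluster number from 0 to 8, a cell cycle phase and a column named DF1, per the file headers. In every cell of that table the sum of the matrix equalled the table's own UMI total, and each cell had at least 800 genes. The deposited receptor table gives UMI counts per assembled contig, and every contig in it is productive, per the file headers. Of the stored matrix entries 1.63% were 0, and Sparc, an abundant fibroblast transcript, had 2 UMIs in the used cells of isotype 1 against 3615 in its other barcodes. Whether background RNA was subtracted before deposit is not given in the sources used here.

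The cells of the metadata table were used. The clusters carry no names, so lineages were read from marker genes fixed before the data were examined, as were the gene lists, the comparisons, the tests and the rule for named genes. Clusters 0, 3 and 6 were taken as CD8, 1 and 7 as conventional CD4 and 2 as regulatory T cells. Clusters 4, 5 and 8 hold both lineages, and their cells were assigned by their own Cd4 UMIs against Cd8a plus Cd8b1 UMIs, and to regulatory T cells by a Foxp3 UMI. A UMI of Foxp3 was found in 81.5% of regulatory, 1.60% of CD8 and 1.82% of conventional CD4 T cells. In CD8 T cells 4.38% of cells had more Cd4 than Cd8 UMIs. Library codes were matched to the groups by the sample titles.

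UMI counts were summed per mouse and class. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM factors, filterByExpr defaults) and Benjamini-Hochberg adjustment at 0.05, with receptor and immunoglobulin segments left out. All tests were two-sided, and positive changes mean higher with anti-ACBP. The square root of the common dispersion was 0.122 in CD8, 0.129 in conventional CD4 and 0.122 in regulatory T cells. Differences in change between 2 classes were tested as an interaction with the mouse as a block. Gene lists with at least 5 tested members, of 30 lists, were tested with camera in limma 3.58.1 (preset correlation 0.01), with fry and an estimated correlation beside it. The other lists, among them B cell, neutrophil, endothelial and GABA type A receptor genes, had too few tested members. Changes of whole classes were compared with the 9 other splits of the 6 mice.

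The genes named in the text are Dbi, Pdcd1, Gzmb, Ifng, Foxp3 and Mki67 in each class. To these come the 10 higher and 10 lower genes with the largest absolute log2 fold change among those that passed, averaged at least 10 CPM in a group and did not overlap, and up to 4 members with the smallest p of each list that passed. Genes named only by a number and mitochondrially encoded genes were counted and not named. Of the genes that meet this rule, 1 is not reported here. Genes named for an overlap, a difference between classes, a list direction or another cell type outside this rule were chosen after their values were seen. Gene families such as the granzymes and Klr genes could share reads, and how the counting treated those is not given in the sources used here.

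Shares were taken within CD4 and within CD8 cells, since the sort set their ratio, and compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1. Clusters with called genes among their 10 top genes were left out of the shares. This exclusion depends on the gene results and was not part of the tests fixed in advance, which covered all classes. Clones were cells with 1 TRB chain and the same V gene and CDR3 nucleotide sequence, and each class was thinned to its smallest library over 100 draws. For the Mki67 shares each cell was thinned to 2000 UMIs, and cells below that were left out. A second clustering, chosen after seeing the data, left out the called genes and used 2000 variable genes (Scanpy 1.11.5), 30 principal components, an unweighted graph of 15 neighbours and a Leiden resolution of 0.6 (igraph 0.11.9). Its cluster sizes depended on the random seed, and small numeric changes altered them in an earlier version, so it was repeated with 10 seeds. In each, a cluster was found by the marker genes given, which were chosen after a first clustering was seen. Scrublet marked 3 of the 30749 cells as doublets and so has not worked here, and the 1028 cells with 2 or more TRB chains were used in its place in an alternative. DF1 was FALSE in 2407 cells, with a median of 9970 UMIs against 5948 in the others, and these cells were kept, since its meaning is not given in the sources used here.

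The summed depth ran from 14128170 to 37527109 UMIs in CD8, from 4209645 to 16918940 in conventional CD4 and from 2454740 to 16156656 in regulatory T cells. The edgeR steps were tested on simulated data with 200 changed genes in 5 simulations per class. They recovered 71.8% of 2-fold changes in CD8, 75.2% in conventional CD4 and 73.8% in regulatory T cells, and 48.8%, 35.6% and 30.8% of 1.5-fold changes. False calls made up 8.36%, 10.8% and 11.5% of calls. Interactions of 2-fold were recovered in 60.5% for CD8 and 53.0% for regulatory against conventional CD4 T cells.

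Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, the replicate number as a block, classes by each cell's own UMIs, removal of doublets, cycling cells or shallow cells, tested receptor segments, other clone definitions and leaving out each mouse. Further ones, chosen after seeing the data, left out DF1 FALSE cells, the heat-shock cluster, the 10 largest clones or all but the largest cluster. Another of these kept only cells whose own UMIs matched their lineage. It left out cells of the other lineage and cells with equal or no Cd4 and Cd8 UMIs. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, Matplotlib 3.10.9 and R 4.3.3. Receptor contigs of barcodes outside the used cells were left out of the comparisons. The cycling cells removed were those in S or G2M phase by the authors' calls and all cells of cluster 4.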

Results

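The series measured single-cell gene expression and T cell receptor sequences in T cells sorted from MCA205 tumours, a fibrosarcoma line grown under the skin of C57Bl/6 mice. Each mouse was injected with 300000 tumour cells, received 10 mg/kg of oxaliplatin (a platinum chemotherapy) 8 days later, and 200 µg of an antibody to PD-1 (an inhibitory receptor of T cells) after another 8 days. In 3 mice an antibody neutralised acyl-CoA binding protein, the product of Dbi, and 3 mice received the isotype IgG2a, each at 2.5 mg/kg every 2 days from 2 days before chemotherapy to 1 day before immunotherapy. Tumours were collected 2 days after immunotherapy, and sorted CD4 and CD8 T cells were mixed at equal numbers before 10000 cells per mouse were loaded. The comparisons ask how tumour-infiltrating T cells of mice given anti-ACBP differ from those of isotype controls under the same chemoimmunotherapy.

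The 6 expression libraries held 30749 cells that the authors kept, from 2923 to 7238 per library. Of these, 16945 fell in CD8 T cells, 8902 in conventional CD4 T cells and 4706 in regulatory T cells, and 196 cells had no class. The isotype libraries 1, 2 and 3 held 65519423, 30008177 and 27791735 UMIs (unique molecules counted). The anti-ACBP libraries 1, 2 and 3 held 53150273, 28037851 and 34330706. Median UMIs per cell were 7148, 4556 and 4516 in the isotype libraries and 6603, 7682 and 6676 in the anti-ACBP libraries. The ratio of CD8 to CD4 cells, which the mixing step sets was not compared.

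In CD8 T cells the genes that rose with anti-ACBP included Fosb and S1pr1, and those that fell included Prdm1 and Hk2. Fosb, a subunit of the AP-1 transcription factor, rose from 14.9 ± 3.04 to 49.9 ± 4.63 CPM (SD, n = 3 mice each), a log2 fold change of 1.73 ± 0.14 (SE; edgeR adjusted p = 0.00571). S1pr1, the receptor that lets T cells leave tissue along sphingosine-1-phosphate, rose from 9.43 ± 0.677 to 25.3 ± 5.34 CPM (SD, n = 3). Prdm1, which encodes Blimp-1, a regulator of effector differentiation and exhaustion, fell from 54.8 ± 10.4 to 21.1 ± 2.89 CPM (SD, n = 3), a log2 fold change of -1.37 ± 0.15 (SE; edgeR adjusted p = 0.0127). Hk2, the hexokinase that commits glucose to glycolysis, fell from 45.2 ± 4.46 to 19.8 ± 0.597 CPM (SD, n = 3), a log2 fold change of -1.19 ± 0.09 (SE; edgeR adjusted p = 0.00527). Other genes that rose were Itgax (an integrin chain, log2 fold change 1.47), Csf1 (a growth factor of macrophages, 1.41), Egr1 (an immediate early transcription factor, 1.12), Atf3 (a stress-induced transcription factor, 1.09), Ralgds (1.10), Xylt1 (0.98), Frmd4b (0.98) and Hexim1 (0.96). Hilpda, a lipid droplet protein induced by hypoxia, fell from 371 ± 91.1 to 155 ± 13.5 CPM and Ddit4, an inhibitor of mTORC1, from 337 ± 46.7 to 142 ± 18.9 CPM (SD, n = 3). Other genes that fell were Tmem273 (-1.33), Abhd18 (-1.30), Pdxp (-1.15), Pim3 (a survival kinase, -1.03), Slc2a1 (the glucose transporter GLUT1, -1.01) and Fosl2 (an AP-1 subunit, -0.99).

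Across the fixed gene lists in CD8 T cells, 12 of 25 tested lists passed the camera test, 6 toward higher and 6 toward lower expression. None passed with an estimated correlation, where the adjusted p of these 12 ran from 0.404 to 0.679. Of 34 tested genes of glycolysis and hypoxia, 6 fell, none rose and 28 did not pass, and 17 were lower adjusted over the list alone. The median log2 fold change of that list was -0.31 (camera adjusted p = 6.6e-13; adjusted p = 0.404 with an estimated correlation), with Pdk1, a kinase that inhibits pyruvate dehydrogenase, at -0.73 ± 0.09 (SE). Of 50 cell cycle genes, 2 fell, Tubb5 (-0.56) and Top2a (-0.64), 48 did not pass, and 31 were lower adjusted over the list alone. All 50 had negative changes, with a median of -0.43 (camera adjusted p = 7.7e-18; adjusted p = 0.404 with an estimated correlation). Of 14 genes of progenitor-exhausted and stem-like cells, 2 rose, the chemokine receptor Cxcr3 (0.94) and the interleukin-7 receptor Il7r (0.49), and 7 were higher adjusted over the list alone (camera adjusted p = 0.00216; adjusted p = 0.404 with an estimated correlation).

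Of 23 genes of early T cell activation in CD8 T cells, 2 rose, Fosb and Egr1, with 8 higher and 2 lower adjusted over the list alone (median 0.24; camera adjusted p = 0.000469; adjusted p = 0.404 with an estimated correlation). Of 43 type I interferon response genes, 1 fell, Samd9l (-0.60), and 10 were lower adjusted over the list alone (median -0.18; camera adjusted p = 0.000453; adjusted p = 0.422 with an estimated correlation). Of 12 markers of natural killer and innate-like T cells, 2 fell, Fcer1g (-0.86) and Klre1 (-0.48), and 2 were lower adjusted over the list alone (camera adjusted p = 0.00655; adjusted p = 0.404 with an estimated correlation). Fcer1g and Klre1 were also among the 10 top genes of CD8 clusters 3 and 0, and the dendritic marker Itgax among those of CD8 cluster 6. Of 28 genes of p53 and apoptosis, 1 rose, the death receptor Fas (0.57), and 7 were higher adjusted over the list alone (camera adjusted p = 0.00163; adjusted p = 0.404 with an estimated correlation). The lists of cytotoxic effector genes (median 0.14, camera adjusted p = 0.0421), autophagy and lysosome genes (median 0.10, 0.00655) and dendritic cell markers (median 0.79, 0.00655) passed toward higher expression. Their adjusted p with an estimated correlation were 0.404, 0.466 and 0.404. Lipid and cholesterol synthesis (median -0.15, camera adjusted p = 0.0421) and ribosomal protein genes (median -0.08, 3.3e-06) passed toward lower expression. Their adjusted p with an estimated correlation were 0.679 and 0.466. Adjusted over the list alone, no gene of the cytotoxic, lipid or ribosomal lists passed, 1 autophagy gene was lower and 1 dendritic marker, Itgax, was higher, while the class II gene H2-Eb1 in that list was at 1.77 and did not pass.

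Counts summed per mouse over CD8 T cells gave 109 genes with an edgeR adjusted p under 0.05, of 11731 tested, 57 higher and 52 lower with anti-ACBP. All 109 had groups that did not overlap, against 24.0% of all tested genes and a 10% share by chance. Here and in the other classes the genes were selected by p on the same values, which favours such groups. Among the genes fixed for every class, Pdcd1 had a log2 fold change of -0.09 ± 0.09 (SE), Gzmb 0.16 ± 0.30, Ifng 0.19 ± 0.35, Dbi -0.16 ± 0.11 and Foxp3, which averaged 3.76 CPM in isotype cells, 0.76 ± 0.57, none of which passed. Mki67, a marker of proliferation, was at 242 ± 35.8 CPM in isotype and 146 ± 26.1 CPM in anti-ACBP cells (SD, n = 3; edgeR adjusted p = 0.0708). The count depended on single mice, from 0 edgeR genes without isotype 3 (1498 at an unadjusted p under 0.05) to 750 without isotype 1. In cells outside the 10 largest clones of each mouse 7 genes passed. All 108 of the 109 genes that were still tested kept their direction, with a median of 0.965 of their log2 fold change.

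In conventional CD4 T cells the largest increase was that of Lmna and the smallest p among decreases that of Ddit4. Lmna, which encodes the nuclear lamins A and C, rose from 30.6 ± 6.55 to 141 ± 16.0 CPM (SD, n = 3), a log2 fold change of 2.21 ± 0.16 (SE; edgeR adjusted p = 0.00213). Ddit4 fell from 488 ± 38.2 to 223 ± 18.4 CPM (SD, n = 3), a log2 fold change of -1.13 ± 0.09 (SE; edgeR adjusted p = 0.00213). Genes that rose also included Fosb (1.78), Emp1 (a membrane protein, 1.36), Atf3 (1.29), the zinc exporter Slc30a1 (1.11), Txnip (an inhibitor of thioredoxin and glucose uptake, 1.11), Klf10 (a TGF-beta-induced transcription factor, 1.04), Dnajb9 (a chaperone of the endoplasmic reticulum, 0.90) and Rgcc (0.88). Pdxp (-1.23), Abhd18 (-1.15), the cell cycle inhibitor Cdkn2d (-0.78), Zbtb7b (-0.78), Pdk1 (-0.77), Pfkfb3 (-0.74), Zfp654 (-0.74) and the mitochondrial carrier Ucp2 (-0.52) fell. Zbtb7b encodes ThPOK, the transcription factor that fixes the CD4 lineage.

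In conventional CD4 T cells, 5 of 25 tested lists passed the camera test, 2 toward higher and 3 toward lower expression, and none passed with an estimated correlation, where their adjusted p ran from 0.662 to 0.730. Of 33 genes of glycolysis and hypoxia, 3 fell, Ddit4, Pdk1 and Pfkfb3, and 30 did not pass, with 9 lower adjusted over the list alone (median -0.13; camera adjusted p = 3.2e-05; adjusted p = 0.662 with an estimated correlation). Of 23 genes of early T cell activation, 2 rose, Fosb and the interleukin-2 receptor chain Il2ra (0.73), with 7 higher and 1 lower adjusted over the list alone (median 0.46; camera adjusted p = 1.8e-06; adjusted p = 0.662 with an estimated correlation). None of 50 cell cycle genes passed over all genes and 13 were lower adjusted over the list alone (median -0.52; camera adjusted p = 3.5e-17; adjusted p = 0.662 with an estimated correlation). None of 28 p53 and apoptosis genes passed over all genes and 8 were higher adjusted over the list alone (median 0.27; camera adjusted p = 2.3e-05; adjusted p = 0.662 with an estimated correlation). None of 43 type I interferon response genes passed by either adjustment, adjusted over the list alone included (median -0.20; camera adjusted p = 0.000382; adjusted p = 0.730 with an estimated correlation).

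Sums over conventional CD4 T cells gave 36 genes with an edgeR adjusted p under 0.05, of 10933 tested, 27 higher and 9 lower, all with groups that did not overlap (21.1% of all tested genes, 10% by chance). Pdcd1 (-0.13 ± 0.12 SE), Gzmb (0.69 ± 0.40), Ifng (0.45 ± 0.12), Foxp3 (0.45 ± 0.35), Mki67 (-0.69 ± 0.28) and Dbi (-0.26 ± 0.09) did not pass. In this class 12.5% of cells carried more Cd8 than Cd4 UMIs. By mouse the shares were 11.96, 4.685 and 17.78% in isotype and 14.24, 20.69 and 15.45% in anti-ACBP mice. How far this difference bears on the changes in this class was not tested. On average 50.4 ± 2.84% (isotype) and 48.8 ± 5.82% (anti-ACBP) of its receptor-typed cells had a TRB chain also seen in CD8 cells of the same mouse (SD, n = 3). For that count 1 such CD8 cell was enough. Whether these cells were misassigned, doublets or mixed between barcodes was not tested. With only cells whose own UMIs matched the CD4 lineage 4 genes passed, and with 1 mouse left out from 2 (without isotype 3) to 139 (without isotype 1).

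Regulatory T cells showed the most genes that passed. Socs1, an inhibitor of cytokine signalling, rose from 88.0 ± 13.8 to 263 ± 12 CPM (SD, n = 3), a log2 fold change of 1.58 ± 0.11 (SE; edgeR adjusted p = 0.000168). Ddit4 fell from 1423 ± 192 to 623 ± 32.0 CPM (SD, n = 3), a log2 fold change of -1.19 ± 0.10 (SE; edgeR adjusted p = 0.000495). Dbi, the gene of the neutralised protein, fell from 253 ± 9.61 to 182 ± 22.8 CPM (SD, n = 3), a log2 fold change of -0.47 ± 0.10 (SE; edgeR adjusted p = 0.0350). Ikzf2, which encodes Helios, a transcription factor of stable regulatory T cells, fell (-0.43 ± 0.10 SE; edgeR adjusted p = 0.0481), while Foxp3 had a log2 fold change of 0.22 ± 0.09 (SE) that did not pass.

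Among genes of at least 10 CPM in a group, the largest increases in regulatory T cells were those of Atf3 (2.11), the granzyme gene Gzmc (2.02), Fosb (1.90), the kinase Sgk1 (1.72), Egr1 (1.71), the protease inhibitor Serpine2 (1.62), Socs1, Klrk1 (the activating receptor NKG2D, 1.48), Lmna (1.39) and Irs2 (an adaptor of insulin signalling, 1.39). Gzmc belongs to a family of near-identical granzyme genes, so reads could be split among its members. The largest decreases in that set were mostly those of genes of cell division, Sapcd2 (-1.76), Stil (-1.47), Kif18b (-1.44), Kif4 (-1.31), Cdca2 (-1.24), Ska1 (-1.18) and Plk1 (-1.18), with Bambi (a decoy receptor of TGF-beta signalling, -1.72), the enolase Eno3 (-1.40) and Ddit4. Of 50 cell cycle genes, 14 fell, none rose, 36 did not pass and 40 were lower adjusted over the list alone. All 50 had negative changes, with a median of -0.92 (camera adjusted p = 7.5e-22; adjusted p = 0.256 with an estimated correlation). Of 34 genes of glycolysis and hypoxia, 7 fell, including Pdk1 (-1.05), Hk2 (-0.90) and Tpi1 (-0.59), and 10 were lower adjusted over the list alone (median -0.27; camera adjusted p = 4.7e-08; adjusted p = 0.25 with an estimated correlation).

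Of 23 genes of early T cell activation in regulatory T cells, 9 rose, among them Irf4 (0.67), Cd69 (0.55) and Icos (0.44), and 1 fell, the AP-1 subunit Junb (-0.63), with 11 higher and 1 lower adjusted over the list alone (median 0.44; camera adjusted p = 5.3e-09; adjusted p = 0.156 with an estimated correlation). Of 24 cytotoxic effector genes, 4 rose, including Tbx21, the T-helper 1 transcription factor T-bet (0.73), and Klrk1, and 6 were higher adjusted over the list alone (median 0.57; camera adjusted p = 2.4e-07; adjusted p = 0.25 with an estimated correlation). With only cells whose own UMIs matched the CD4 lineage, Tbx21 (0.76) and Socs1 (1.61) passed, and Gzmc (1.52) and Klrk1 (1.75) did not. Cells with equal or no Cd4 and Cd8 UMIs were also left out there. Of 40 type II interferon response genes, 5 rose, including Socs1, Cd274 (the ligand PD-L1, 0.69) and the GTPase gene Igtp (0.57), and 8 were higher and 2 lower adjusted over the list alone (median 0.06; camera adjusted p = 0.0301; adjusted p = 0.330 with an estimated correlation). Of 45 autophagy and lysosome genes, 3 rose, including the autophagy receptor Sqstm1 (0.83), and 8 were higher adjusted over the list alone (median 0.17; camera adjusted p = 0.000106; adjusted p = 0.156 with an estimated correlation). Of 27 genes typical of regulatory T cells, 3 rose, Icos, Tnfrsf9 (the costimulatory receptor 4-1BB, 0.38) and the checkpoint receptor Tigit (0.46), and 1 fell, Ikzf2, with 5 higher and 2 lower adjusted over the list alone (median 0.23; camera adjusted p = 0.00659; adjusted p = 0.326 with an estimated correlation). Of 28 p53 and apoptosis genes, 2 rose, including the survival gene Mcl1 (0.50), and 4 were higher adjusted over the list alone (median 0.18; camera adjusted p = 0.00659; adjusted p = 0.326 with an estimated correlation).

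In all, 20 of 23 tested lists passed in regulatory T cells, 14 toward higher and 6 toward lower expression, and none with an estimated correlation, where their adjusted p ran from 0.156 to 0.568. The other lists that passed toward higher expression were those of exhaustion and inhibitory receptors (median 0.34), naive and central memory cells (0.39), progenitor-exhausted and stem-like cells (0.40), T-helper 1 (0.28), T-helper 2 (0.38) and follicular helper cells (0.18), tissue residency (0.31) and dissociation and heat stress (0.09). In the progenitor-exhausted list 2 genes rose and Myb, a transcription factor of stem-like T cells, fell (-0.54). Those that passed toward lower expression were type I interferon response (-0.18), in which Irf9 rose (0.44), oxidative phosphorylation (-0.07), lipid and cholesterol synthesis (-0.22) and ribosomal proteins (-0.14).

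Sums over regulatory T cells gave 348 genes with an edgeR adjusted p under 0.05, of 10417 tested, 213 higher and 135 lower, all with groups that did not overlap (26.5% of all tested genes, 10% by chance). Pdcd1 (0.31 ± 0.10 SE), Gzmb (0.57 ± 0.23), Ifng (2.01 ± 0.77) and Mki67 (-1.12 ± 0.29; 316 ± 103 CPM in isotype and 145 ± 27.7 CPM in anti-ACBP cells, SD, n = 3) did not pass. With 1 mouse left out the count ran from 44 genes (without anti-ACBP 2) to 772 (without isotype 2). Without cycling cells 163 genes passed, of which 104 were among the 348. Regulatory T cells with more Cd8 than Cd4 UMIs made up 4.30, 2.05 and 5.21% in isotype and 6.01, 7.95 and 6.59% in anti-ACBP mice. With only cells whose own UMIs matched the lineage 213 genes passed. That setting also left out the 25.4% of cells with equal or no Cd4 and Cd8 UMIs. Cd8a was at 1.76 ± 0.39 (SE; edgeR adjusted p = 0.0710) and Cd8b1 at 1.06 ± 0.25 (SE; edgeR adjusted p = 0.0701), and neither passed. Of markers of other cells, the neutrophil gene Mmp9 rose (1.12 ± 0.24 SE). Spp1 (4.60 ± 0.97 SE) of the macrophage list and Klri2, Cd160 and Klre1 of the natural killer list (1.31, 1.38 and 0.85) did not pass. In these data Spp1 and Klre1 were also among the 10 top genes of clusters 3 and 0, taken as CD8.

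**Figure D1:**
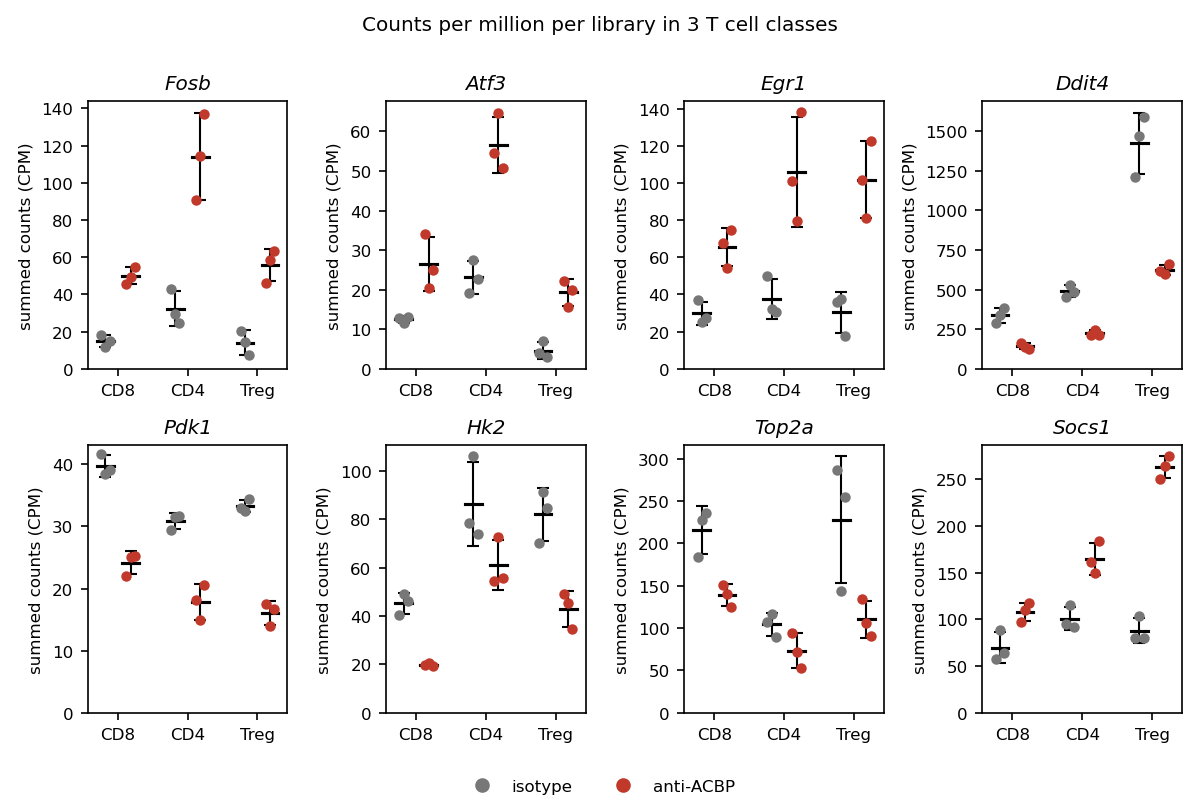
CPM (linear axes) of 8 genes per library in CD8, conventional CD4 (CD4) and regulatory (Treg) T cells, with grey points for isotype and red points for anti-ACBP mice, and black bars for the mean and SD of 3 mice. Ddit4 and Pdk1 were lower and Fosb and Atf3 higher in all 3 anti-ACBP mice than in any isotype mouse in each class.

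**Figure D2:**
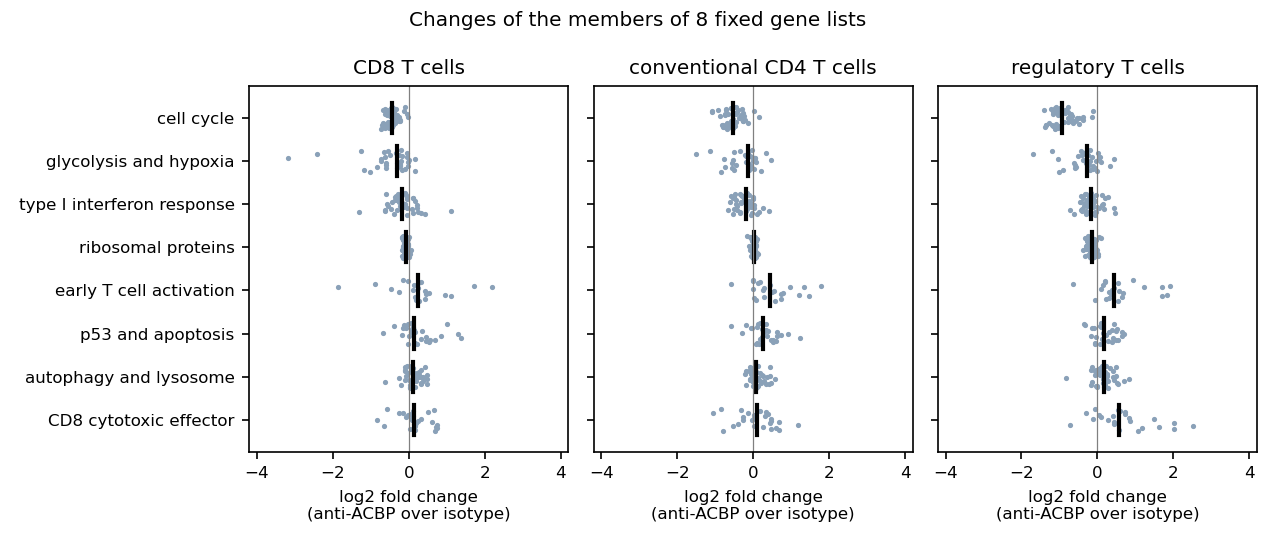
Log2 fold change (anti-ACBP over isotype) of each tested member of 8 fixed gene lists in the 3 T cell classes, with a point per gene and a black bar at the list median. All 50 cell cycle genes lay below 0 in CD8 and in regulatory T cells.

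The 3 classes shared part of these genes. Genes higher in all 3 included Atf3, Fosb and Resf1, and Abhd18, Ddit4 and Pdk1 were lower in all 3. CD8 and regulatory T cells shared 16 higher and 18 lower genes, where independent lists would share 1.08 and 0.631. Conventional CD4 and regulatory T cells shared 19 higher and 5 lower genes (0.552 and 0.119 if independent), and CD8 and conventional CD4 T cells shared 5 higher and 4 lower genes (0.140 and 0.0416). No gene passed in opposite directions in any pair of classes. The classes come from the same mice and are not independent, and the number shared with no effect of the antibody was not simulated. The covariance of changes across genes was 0.0409 between CD8 and regulatory T cells in the real grouping and at most 0.0145 in the 9 other splits of the mice. It was 0.0401 and at most 0.0186 between conventional CD4 and regulatory T cells, and 0.0343 and at most 0.0169 between CD8 and conventional CD4 T cells. The correlation was 0.688 and at most 0.631, 0.678 and at most 0.710, and 0.761 and at most 0.697 for these pairs in the same order. Another split exceeded the real one for conventional CD4 and regulatory T cells.

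A test of the difference in change between classes asked whether regulatory and conventional CD4 T cells responded unequally. Socs1 rose more in regulatory T cells (1.58 against 0.71 in conventional CD4 T cells, difference 0.90 ± 0.09 SE; edgeR adjusted p = 0.000925). Lmna rose less in them (1.39 against 2.21, difference -0.78 ± 0.08 SE; edgeR adjusted p = 0.000925). Tbx21 rose in regulatory T cells and was -0.13 in conventional CD4 T cells, a difference of 0.89 ± 0.14 (SE; edgeR adjusted p = 0.0329). In all 23 genes differed, 12 with a higher and 11 with a lower change in regulatory T cells, among the first Klf6, the chemokine receptor gene Ccr8 and the chemokine gene Xcl1. The Xcl1 difference was 2.78 ± 0.47 (SE), and this gene was too low to be tested in regulatory T cells alone. Between CD8 and conventional CD4 T cells 1 gene differed, the metallothionein gene Mt1, with changes of -0.42 and 0.56 (difference -0.93 ± 0.10 SE; edgeR adjusted p = 0.0117). With 1 mouse left out the number of genes ran from 4 (without anti-ACBP 3) to 301 (without isotype 2) in the first test. In the second it ran from 0 edgeR genes (without isotype 3 or anti-ACBP 3, with 803 and 848 at an unadjusted p under 0.05) to 19 (without isotype 1).

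Regulatory T cells made up 38.9 ± 9.71% of CD4 T cells in isotype and 30.2 ± 9.88% in anti-ACBP mice (SD, n = 3; two-sided exact permutation p = 0.4, where 0.1 is the smallest possible). Cluster 1 of the authors, marked by Ccr7 and Tcf7, genes of naive and central memory cells, held 75.5 ± 4.15% of conventional CD4 T cells in isotype and 83.1 ± 2.10% in anti-ACBP mice (SD, n = 3; exact permutation p = 0.1, adjusted p = 0.6 over 8 shares). Cluster 7, marked by Penk, Tnfsf11 and Il13, held 10.2 ± 2.78% and 6.62 ± 1.52% (SD, n = 3; exact permutation p = 0.2). The other 5 shares, of clusters 5 and 8 in CD8 and of clusters 4, 5 and 8 in conventional CD4 T cells, had an exact permutation p from 0.3 to 0.9. Clusters 0, 3, 4 and 6 of CD8 T cells are defined in part by genes that changed between the groups, and their sizes were not compared. The adjustment over 8 shares thus covers fewer shares than the one fixed in advance.

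After each cell was thinned to 2000 UMIs, cells with a UMI of Mki67 made up 18.7 ± 4.60% of regulatory T cells in isotype and 9.20 ± 1.26% in anti-ACBP mice (SD, n = 3; exact permutation p = 0.1). In CD8 T cells the shares were 15.9 ± 1.86% and 10.2 ± 1.15%, and in conventional CD4 T cells 8.37 ± 1.08% and 5.23 ± 1.09% (SD, n = 3; exact permutation p = 0.1 each). Without thinning the shares were 32.1 ± 7.88% and 20.1 ± 4.19% of regulatory, 26.1 ± 1.33% and 20.1 ± 1.62% of CD8 and 14.3 ± 3.85% and 10.7 ± 0.872% of conventional CD4 T cells (SD, n = 3; exact permutation p = 0.1, 0.1 and 0.3). By the authors' calls, cells in S or G2M phase made up 33.6 ± 3.02% and 18.4 ± 3.71% of regulatory, 38.5 ± 7.15% and 27.7 ± 0.278% of CD8 and 22 ± 0.558% and 18.4 ± 2.73% of conventional CD4 T cells (SD, n = 3; exact permutation p = 0.1, 0.1 and 0.2). Cluster 1, which has few cycling cells, had a thinned share of 3.84%. Thinning left out 129 isotype and 35 anti-ACBP regulatory T cells, 286 and 186 CD8 T cells, and 283 and 85 conventional CD4 T cells.

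**Figure D3:**
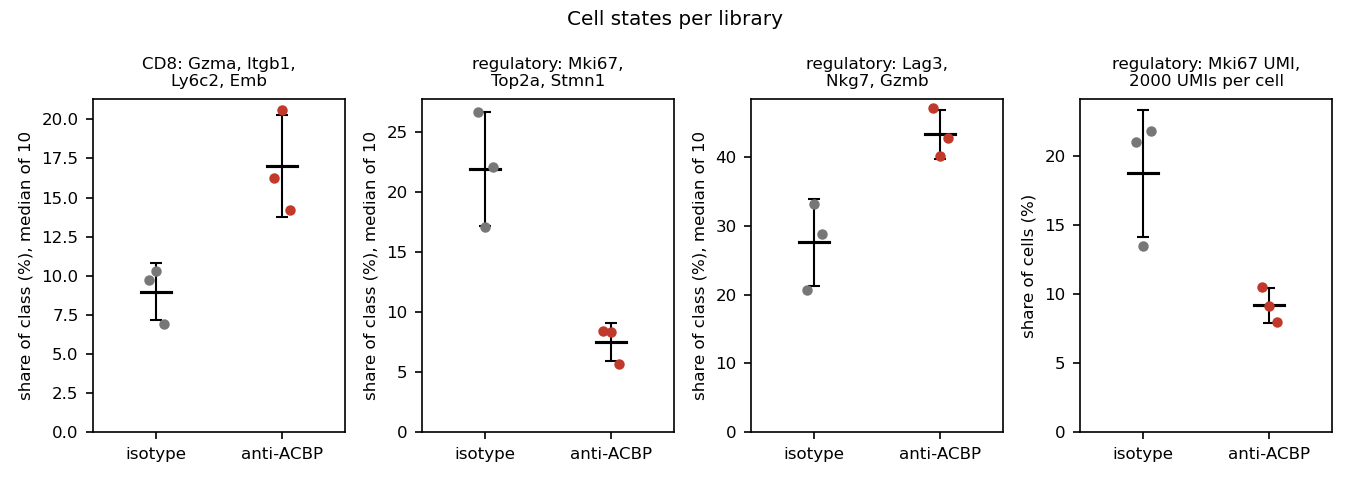
Share of cells (%) per library in a CD8 cluster and 2 regulatory T cell clusters, as the median of 10 clusterings that left out the called genes. Beside them is the share of regulatory T cells with an Mki67 UMI at 2000 UMIs per cell. Grey points are isotype and red points anti-ACBP mice, with black bars for the mean and SD of 3 mice. The Mki67 shares were 18.7% in isotype and 9.20% in anti-ACBP mice, with no overlap between the groups.

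The share of receptor-typed cells in clones of 2 or more cells, defined by the TRB nucleotide sequence, was high in every class and overlapped between the groups. With each mouse thinned to 1345 cells it was 93.0 ± 1.01% of CD8 T cells in isotype and 91.2 ± 1.42% in anti-ACBP mice (SD, n = 3; exact permutation p = 0.2). At 635 cells it was 75.4 ± 5.17% and 71.5 ± 2.06% of conventional CD4 T cells (SD, n = 3; exact permutation p = 0.4), cells that share a TRB chain with CD8 T cells included. At 229 cells it was 60.2 ± 7.49% and 63.2 ± 3.73% of regulatory T cells (SD, n = 3; exact permutation p = 0.5). The inverse Simpson index, which falls as few clones dominate, was 27.5 ± 4.33 and 35.2 ± 16.8 in CD8 T cells (SD, n = 3; exact permutation p = 0.6).

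**Figure D4:**
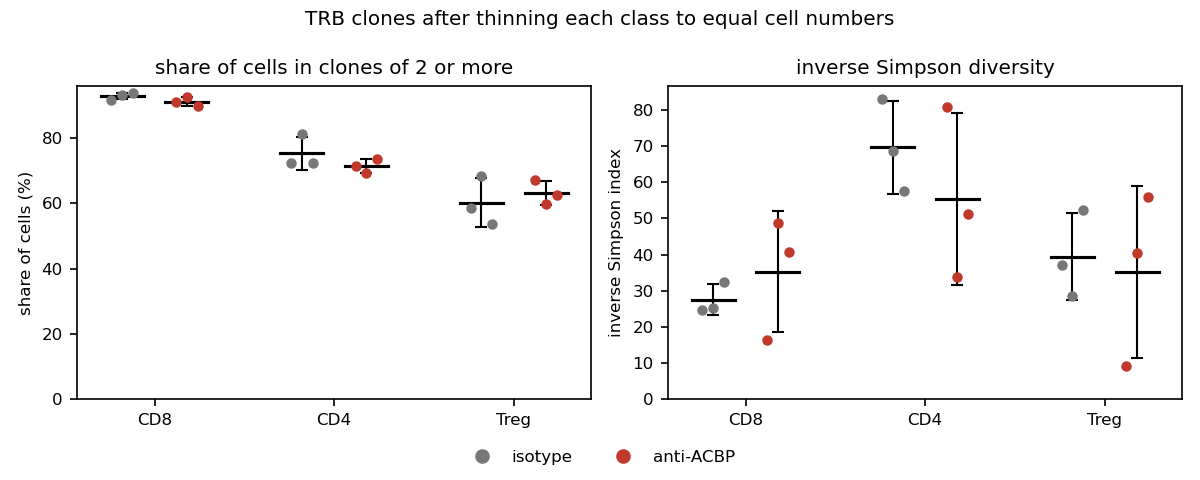
Share of cells in clones of 2 or more (%, left) and inverse Simpson diversity index (right) of TRB clones in CD8, conventional CD4 (CD4) and regulatory (Treg) T cells after thinning to equal cell numbers, with grey points for isotype and red points for anti-ACBP mice, and black bars for the mean and SD of 3 mice. The groups overlapped in every class, with CD8 shares from 89.8% to 93.8%.

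The list of fatty acid oxidation and acyl-CoA metabolism, which holds Dbi, passed camera in no class (median -0.01 in CD8, -0.04 in conventional CD4 and 0.00 in regulatory T cells). By fry it passed in conventional CD4 T cells toward lower expression (fry adjusted p = 0.0161), the only list that did in that class. Of its members Ucp2 fell in conventional CD4 and Dbi in regulatory T cells. Median, mean and test differed in sign for dissociation and heat stress in CD8 (median -0.01, mean 0.14) and conventional CD4 T cells (median -0.01, mean 0.13). They also differed for fatty acid oxidation in CD8, for exhaustion, naive and tissue residency genes in conventional CD4 and for T-helper 17 and dendritic cell genes in regulatory T cells, none of which passed.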

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

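Of the tests in this part, the equal weighting of cells was chosen before its result was seen, and the tests of cluster mix, heat-shock genes, large clones and splits of the mice were chosen after. For the cluster mix, 10 clusterings took the place of 1 after its result was seen to vary from run to run. The change with anti-ACBP differed between CD8 and conventional CD4 T cells for 1 gene, Mt1, and between regulatory and conventional CD4 T cells for 23 genes, by a test of the difference itself. Outside the cells used, 1068 barcodes carried a productive TRB chain, from 3.23% to 5.18% of the TRB barcodes per library. The 6 mice allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 109 edgeR genes in CD8, 36 in conventional CD4 and 348 in regulatory T cells, and the highest of the others 0 in each, so that 1 split gave as many. For the lists it gave 12, 5 and 20 against a highest other of 10, 11 and 13, and as many lists came from 1, 9 and 1 splits. For the differences in change it gave 1 against 2 for CD8 and 23 against 12 for regulatory T cells, with as many genes in 4 and 1 splits.

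The list of glycolysis and hypoxia passed camera toward lower expression with anti-ACBP in all 3 classes, with 6 of 34 genes lower by edgeR in CD8, 3 of 33 in conventional CD4 and 7 of 34 in regulatory T cells, and in none with an estimated correlation (adjusted p = 0.404, 0.662 and 0.25). With equal weight per cell the list median kept at least 0.893 of its size in every class, which argues against deeper cells weighing more in the sums as the whole cause. With the same mix of clusters it kept at least 0.707 of its size over 10 clusterings, the lowest being in CD8 T cells, which falls short of the 0.75 set for excluding a changed mix, so a changed mix may be a part of it. In the used cells of each library Sparc had 2 to 5 UMIs and Col3a1 2 to 4. Other barcodes held 2414 to 6849 of Sparc and 1010 to 4841 of Col3a1. Background of Sparc and Col3a1 was thus nearly absent from the used cells. These values cannot decide whether background of glycolysis and hypoxia genes was left, since the T cells also express those genes. Spp1, a top gene of CD8 cluster 3, had 1238 to 5422 UMIs in used cells. Whether background was subtracted unevenly before deposit was not tested. An effect of the antibody may account for the pattern but cannot be told from these or from chance among 6 mice.

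Fosb and Atf3, genes of immediate early and stress transcription, were higher with anti-ACBP in all 3 classes. Stress during tissue dissociation may account for this. The median change of 10 heat-shock genes, without the heat-shock cluster, was -0.28 ± 0.08 (SE) in CD8, -0.12 ± 0.16 in conventional CD4 and -0.41 ± 0.33 in regulatory T cells. The error in conventional CD4 T cells left this test undecided. It also covered heat-shock genes alone, while Fosb and Atf3 are other members of the dissociation and heat stress list. Adjusted over that list alone, 8 of its 26 genes were higher and 4 lower in CD8 T cells. The counts were 7 and 2 in conventional CD4 and 9 and 3 in regulatory T cells. Dissociation stress stays open in all 3 classes. With the same mix of clusters the changes of Fosb and Atf3 kept at least 0.728 of their size over 10 clusterings. The lowest was Atf3 in CD8 T cells, which falls short of the same 0.75. An effect of the antibody stays open as well.

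The cell cycle list passed camera toward lower expression with anti-ACBP in regulatory T cells, with 14 of 50 genes lower by edgeR, but not with an estimated correlation (adjusted p = 0.256). With equal weight per cell the list median was 1.14 of that in the sums, which argues against deeper cells weighing more in the sums. Outside the 10 largest clones of each mouse the list median kept 0.981 of its size, which argues against a few large clones. The 2 to 5 UMIs of Sparc in the used cells of each library cannot decide here either whether background of cell cycle genes was left. Uneven subtraction of background and chance among 6 mice were not excluded. An effect of the antibody on cycling may be a candidate explanation as a hypothesis only.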

How the results depend on the processing

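Settings on DF1, lineage match, large clones, the largest cluster and the heat-shock cluster were chosen after seeing the data. The genes that passed and were still tested kept their direction in each setting, except in regulatory T cells without cycling cells (313 of 318) and in 1 random draw of them (327 of 328). Since their groups did not overlap, leaving out 1 mouse could hardly turn them. The other settings used the same mice, so the kept direction is no separate support. DESeq2 gave 481 genes in CD8 and 209 in conventional CD4 T cells. Without the low-count filter, which raises the number of genes tested, the counts were 354, 295 and 820 in CD8, conventional CD4 and regulatory T cells, and 74 and 489 for the differences of CD8 and regulatory against conventional CD4 T cells. Without DF1 FALSE cells 47 genes passed in CD8. With matching lineage UMIs 4 passed in conventional CD4 and 213 in regulatory T cells. By own UMIs 209 passed in regulatory T cells, 10 in their difference and 0 by edgeR in that of CD8. Outside the 10 largest clones 7, 15 and 196 passed, while random draws of as many cells gave 48 to 156, 8 to 58 and 186 to 365. A median of 0.965 of the log2 fold change was kept outside the CD8 clones and 0.977 to 1.02 in the CD8 draws, so the changes stayed about as large. The largest cluster alone gave 20 in conventional CD4, and regulatory T cells without cycling cells 163. For the lists, an estimated correlation gave 0, 0 and 0 and fry 0, 1 and 3. Outside the clones 7 lists passed in CD8, and without cycling cells 10 in regulatory T cells. The lists that passed and were still tested kept their direction, except in regulatory T cells type II interferon response without cycling cells and oxidative phosphorylation outside the clones, neither of which passed there. Clones of 5 or more changed the expanded clone share in CD8 by -5.42 points, and no thinning changed the expanded clone share in Treg by -5.38. Of the 8 shares 1 did not overlap, against 0 by own UMIs and 2 with cells of at least 2000 UMIs, without cycling cells, with a TRB chain or without DF1 FALSE. Leaving out 1 mouse gave 0 to 750 genes in CD8 (0 without isotype 3, 3 without anti-ACBP 2, 10 without anti-ACBP 1, 34 without anti-ACBP 3, 750 without isotype 1). It gave 2 to 139 in conventional CD4 (2 without isotype 3, 4, 9 and 11 without anti-ACBP 1, 2 and 3, 139 without isotype 1). In regulatory T cells it gave 44 to 772 (206, 772 and 52 without isotype 1, 2 and 3, 138, 44 and 45 without anti-ACBP 1, 2 and 3). The differences ranged from 0 to 19 (19 without isotype 1, 0 without isotype 3, 6, 2 and 0 without anti-ACBP 1, 2 and 3) and from 4 to 301 (9, 301 and 10 without isotype 1, 2 and 3, 14 and 4 without anti-ACBP 2 and 3). Lists ranged from 7 (without isotype 2) to 12 in CD8, 7 to 9 (without isotype 3 or anti-ACBP 2) in conventional CD4 and 17 to 19 in regulatory T cells. The shares ranged from 1 to 4 (4 without isotype 2, 2 without isotype 3 or anti-ACBP 1 or 2), the regulatory T cell share of CD4 from -13.7 to -3.22 points, the expanded clone share in CD8 from -2.51 to -1.09 points, the expanded clone share in CD4conv from -5.41 to -0.890 points and the expanded clone share in Treg from -0.272 to 7.08 points. Of genes that did not pass, Ifng in CD8 turned to -0.25 without cycling cells, -0.44 in the largest cluster, -0.03 without isotype 1 and -0.02 without anti-ACBP 1, and ranged from -0.0273 to 0.456 with 1 mouse left out. Gzmb in CD8 turned to -0.06 and -0.11 without the same mice and ranged from -0.11 to 0.39, and Foxp3 in conventional CD4 to -0.34 outside the clones. Except where a construction is named, the cause was not tested.

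With the replicate number as a replicate block 158, 8 and 368 genes passed. The correlations of deviations between equal numbers were 0.238, 0.0139 and -0.0942 in CD8 T cells. They were 0.0930, -0.151 and -0.0105 in conventional CD4 and 0.233, -0.152 and -0.127 in regulatory T cells. With 3 mice per group these values cannot show whether equal numbers pair the mice. Barcodes outside the used cells had a median of 995 UMIs in isotype 1 and 927 in anti-ACBP 1. The median ran from 582 to 615.5 in the other libraries.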

Other observations

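A clustering made without the called genes, chosen after seeing the data and repeated with 10 random seeds, gave differences in cluster shares between the groups. The marker genes of its clusters were chosen after a first clustering was seen. Genes that vary with the called genes remained in it, and the seeds share the same graph. These differences are therefore not independent of the gene results. Shares are the median over seeds, and the exact two-sided permutation p was 0.1 for each share given here, the smallest possible, so none could pass. A CD8 cluster marked by Gzma, Itgb1, Ly6c2 and Emb, genes of effector and migrating T cells, held 9.0 ± 1.81% of CD8 T cells in isotype and 17 ± 3.27% in anti-ACBP mice (SD, n = 3; exact permutation). Its size depended on the seed, with a difference from 6.02 to 14.5 points, and the groups did not overlap in any of the 10. In regulatory T cells a cluster marked by Lag3, Nkg7 and Gzmb held 27.6 ± 6.35% and 43.3 ± 3.54% (SD, n = 3), with a difference from 13.2 to 17.7 points. The cycling cluster of Mki67, Top2a and Stmn1 held 21.9 ± 4.75% and 7.50 ± 1.57% of regulatory T cells, and that of Mki67 and Stmn1 held 14.2 ± 2.98% and 9.95 ± 0.896% of CD8 T cells (SD, n = 3), without overlap in each seed. A cluster marked by the interferon-induced genes Isg15, Ifit1 and Ifit3 held 5.42 ± 1.44% and 2.28 ± 1.49% of regulatory T cells (SD, n = 3), without overlap in 8 of the 10. The interferon clusters of CD8 and conventional CD4 T cells and the cycling cluster of conventional CD4 T cells overlapped between the groups in all 10 seeds. A CD8 cluster chosen by Gzmf and Gzmc was not read, since in 9 of the 10 seeds its 10 top genes also held the mitochondrial gene mt-Cytb and genes named only by a number, and in the other seed it was a different and larger cluster.

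Some receptors recurred between mice. The TRB sequence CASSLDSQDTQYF with TRBV12-2 was found in 703 cells of 4 mice and made up 19.3% of receptor-typed CD8 T cells in anti-ACBP 1. Of the 703 cells, 612 came from anti-ACBP 1, 27 from isotype 1, 21 from anti-ACBP 2 and 43 from anti-ACBP 3. Its most common TRA partner was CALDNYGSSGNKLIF, in 87.5% of its cells with TRA. That share pools all 4 mice, and whether the pairing recurred between mice was not tested. In all 6 mice 8 TRB amino acid sequences were seen, in 1197 cells or 5.10% of those with 1 TRB chain, among them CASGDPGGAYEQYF, whose cells lay mostly in cluster 1. The clone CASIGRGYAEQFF made up 31.9% of regulatory T cells with 1 TRB chain in anti-ACBP 1 and was seen in 1 mouse. Cells with TRAV11 and TRAJ18, the chain of invariant natural killer T cells, numbered 0 or 1 per library. Regulatory T cells that shared a TRB chain with conventional CD4 T cells of their mouse made up 22.8 ± 7.85% in isotype and 12.9 ± 4.32% in anti-ACBP mice (SD, n = 3; exact permutation p = 0.2). Those that shared one with CD8 T cells made up 11 ± 9.01% and 17 ± 22.5% (SD, n = 3; exact permutation p = 0.8), with 42.9% in anti-ACBP 1. A clone counts as shared from 1 cell in the other class. In anti-ACBP 1 all regulatory T cells of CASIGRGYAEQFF count, since 1.79% of its 168 cells fell in CD8. The 42.9% thus rests in large part on that clone. These shares were not thinned to equal cell numbers.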
